A study of Homo sapiens with 5 samples.

How the data were processed

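Total RNA from SEM dCas9-KRAB cells was extracted with Trizol and sequenced as single-end reads of 100 bases on a NovaSeq instrument, per the labels' protocols. The 5 libraries fall into 2 groups by their labelled treatment, with 2 vector control libraries (Lenti) and 3 sgCDK6 libraries. The titles of the latter carry the word left, whose meaning is not given in the sources used here. The replicate numbers used here only name libraries.

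The authors deposited a table of expected counts per gene and a table of TPM per gene for 60754 genes, both gene-level RSEM output with a name that marks them as stranded. Trim Galore, STAR 2.7.1a, GATK 4.1.2.0 and RSEM, with hg19 and GRCh37.p13 as genome builds, are named per the submitters' processing notes, without roles or order, and the annotation release is not given in the sources used here. The deposited expected counts are not normalised and 7.25% to 7.92% of the values in a library were not whole, so they were rounded to whole numbers. The deposited TPM values, made by the authors, sum to the same total in each library and depend on the transcript length that RSEM assigned in each library. Gene symbols were taken from the tables. Transcript length, GC content and coordinates came from a GENCODE annotation on GRCh37, and 98.7% of the tested genes had a GC value.

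Libraries were compared before averaging. Pearson's r of log2 CPM was 0.982 to 0.993 across genes for the 10 pairs of libraries, and the chi-square per gene was at least 15.3, so no pair agreed within sampling noise. Total expected counts ranged from 37640247 to 56255037, and RN7SL1, RN7SL2 and RN7SK took 13.6% to 15.7% of them.

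Differential expression was tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default low-count filter, which kept 17655 genes, and the quasi-likelihood F test. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05, and log2 fold changes are sgCDK6 minus control. CPM values are TMM-scaled. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with CDK6 left out of each list. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in a single direction, were run beside it. Of the 21 lists, 18 had at least 5 tested members. The lists were CDK6 neighbours, G1 regulators, E2F targets, G2/M genes, histones, the KMT2A-rearranged leukaemia programme, reported CDK6 targets, B-lineage, myeloid, T and NK, erythroid and fibroblast genes, p53 targets, interferon response, BCL2 family, MYC and ribosome biogenesis, stress response, cholesterol synthesis, glycolysis, immediate early and mitochondrial genes. With a preset correlation 9 lists passed, none passed with an estimated correlation and 6 passed by fry. Those passing by fry were the G1, E2F, G2/M, myeloid, cholesterol synthesis and immediate early lists (fry adjusted p = 0.0309 to 0.0402). The mitochondrial, histone and neighbour lists did not pass by fry (adjusted p = 0.11, 0.131 and 0.149).

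The test, the lists, the rule for named genes and the first set of other settings were chosen before the data were examined. Named genes were CDK6, its passing neighbours and its flanking genes FAM133B and SAMD9, the 12 largest rises and the 12 largest falls among passing protein-coding genes with a mean of at least 2 CPM and no overlap between groups, and up to 4 passing members of each list by p-value, or the 2 with the smallest p where none passed. Other genes were named after their values were seen: HOXA9, MEIS1, FLT3, CDK4, CCND3, MKI67, TYMS, EGR2, IER2, SHMT2, MT-ND6, CPT1A, TRPM2, the class II genes, the mitochondrial ribosomal RNAs and the small RNAs.

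This first set held DESeq2 1.42.0, RLE and upper-quartile scaling, no filter, a filter of at least 1 CPM in 2 libraries, limma on log2(TPM + 1) and log2(TPM + 0.1), protein-coding genes only, each library left out in turn, a test against a fold of 1.2 and camera with an estimated correlation. After the data were seen, corrections that remove a smooth trend on GC content, or on GC content and length, from each library (lowess span 0.3), a fit with sgCDK6 library 3 alone against both controls, and limma on TPM rescaled to the median gene were added.

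The procedure was tested on simulated data for the same comparison, with 17655 genes of which 200 were changed, in 3 simulations. The changed genes had a mean above 1 CPM, and each gene's spread was set by the fitted trend of spread with expression. Recovery of genes with lower means was not tested. The edgeR test recovered 67.7% of genes changed 1.5-fold and 95.3% of those changed 2-fold, with 8.67 false calls on average. With a GC trend planted, these values were 47%, 93.3% and 116, and with the GC correction they were 68%, 96% and 9.67. The planted trend was the smooth trend fitted to these libraries, of the same form that the correction removes. The simulations therefore cannot show how the correction performs on a trend of another form. A list shifted by -0.4 on the log2 scale was called in 3 of 3 simulations and 0 other lists were called. No GC trend was planted in these list simulations. Genes were drawn independently, whereas the estimated correlation in the data was 0.23 for E2F targets, 0.43 for G2/M genes and 0.81 for histones. The simulations therefore cannot show how the preset correlation performs on such lists. Camera with an estimated correlation, which here rests on 5 libraries in 2 groups, was not run on the simulated data. How often it would find a shifted list is therefore not known. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.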

Results

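RNA-seq was performed on SEM cells, an established B-cell precursor leukaemia line with a KMT2A (MLL) rearrangement, that stably expressed dCas9-KRAB. This fusion of catalytically inactive Cas9 and a KRAB repressor domain silences DNA near the site to which a guide RNA directs it. The control group held 2 libraries from cells labelled as carrying the lentiviral vector, and the sgCDK6 group held 3 libraries from cells carrying a guide against CDK6. Total expected counts were 48219419 and 56255037 in the control libraries and 47377600, 48702071 and 37640247 in sgCDK6 libraries 1, 2 and 3. Nothing states that the libraries came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

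The first question was what CRISPR interference at a HOXA9-bound peak in an intron of CDK6 did to CDK6 itself. CDK6, a cyclin D-dependent kinase of the G1 phase, fell in all 3 sgCDK6 libraries. Its normalised count was 1624 ± 70.2 CPM (SD, n = 2) in the control libraries and 713.6 ± 13 CPM (SD, n = 3) in the sgCDK6 libraries, a fall of 56.1%. The control libraries had 1674 and 1575 CPM and the sgCDK6 libraries 721, 722 and 699 CPM. The log2 fold change was -1.19 (SE 0.08, edgeR adjusted p = 0.0031), and CDK6 had rank 2 by p-value among the 17655 genes tested. CDK6 (ENSG00000105810.9) lies on the minus strand of chromosome 7 from 92234235 to 92465887 in GRCh37, and its longest annotated transcript has 8 exons. The guide sequence and the position of the targeted peak within the intron are not given in the sources used here. In the deposited TPM values CDK6 was 68.7 ± 11.5 (SD, n = 2) in controls and 42.5 ± 9.5 (SD, n = 3) in sgCDK6 libraries, a ratio of 0.619, and with limma on log2(TPM + 1) the change of -0.69 did not pass (adjusted p = 0.165).

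**Figure D1:**
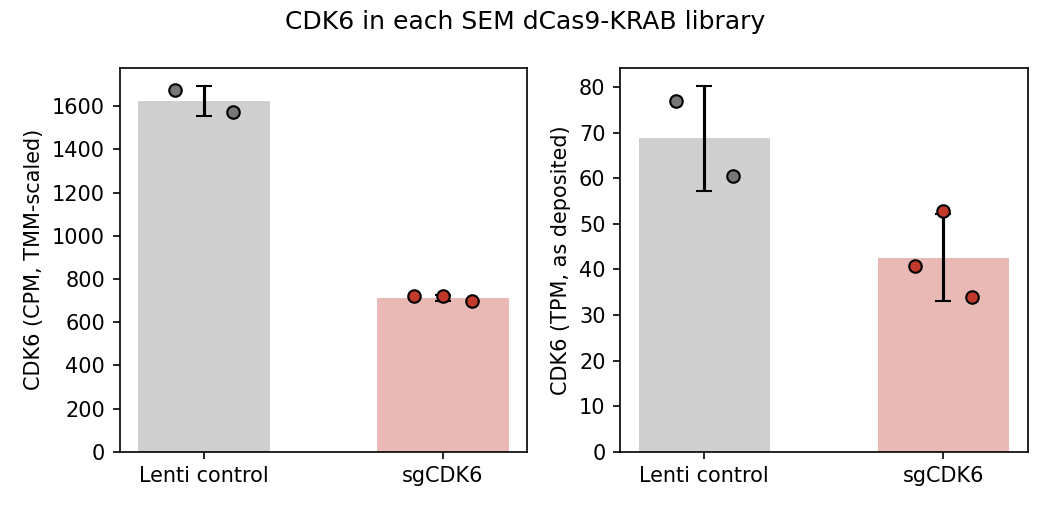
CDK6 in each library as TMM-scaled CPM (left panel) and as deposited TPM (right panel), for the Lenti control (n = 2) and sgCDK6 (n = 3) groups. Bars are group means, error bars are SD and points are libraries; the sgCDK6 libraries sit between 699 and 722 CPM, below both controls at 1575 and 1674 CPM.

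Of the 16 symbols listed for genes near CDK6 on chromosome 7, 12 matched a gene expressed highly enough to test. CYP51A1, a sterol demethylase of cholesterol synthesis, fell (log2 fold change -0.47, SE 0.09, edgeR adjusted p = 0.0347), and it was the only one of the 12 to pass over all genes. Adjusted over the list alone, 2 of the 12 were lower. The genes flanking CDK6 did not pass, with FAM133B at -0.29 (SE 0.11, adjusted p = 0.124) and SAMD9 at -0.24 (SE 0.10, adjusted p = 0.152). As a list the neighbours were lower (median log2 fold change -0.20, camera adjusted p = 0.0174, adjusted p = 0.585 with an estimated correlation). These genes are AT-rich, with a median transcript GC content of 38.5%, and after a correction for GC content chosen after the data were seen the list median was -0.02 and the list's call was lost (camera adjusted p = 0.612). CYP51A1 itself still passed with that correction (-0.34, SE 0.06, edgeR adjusted p = 0.0335). It lies from 91714301 to 91764117, farther from CDK6 than FAM133B, which stood at -0.07 with that correction. CYP51A1 is also in the cholesterol synthesis list, where 5 of 22 members fell and 0 rose. Its fall can therefore not be assigned to the targeted site.

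Across the transcriptome 1008 of 17655 genes passed, 546 higher and 462 lower in sgCDK6 libraries. Among them 136 changed at least 2-fold and 582 less than 1.5-fold. All 1008 had no overlap between the groups' libraries, which held for 51.1% of all genes tested and would hold for 20% by chance. Beside CDK6, the largest falls among protein-coding genes with a mean of at least 2 CPM were in NME1-NME2 (-1.55, SE 0.17), CHI3L2 (-1.37, SE 0.15), PDE5A (-0.99, SE 0.14) and PHLDB2 (-0.90, SE 0.09). The remaining genes of that group were PCLAF, a PCNA-binding protein (-0.75), CDK1, the mitotic kinase (-0.74), the chemokine receptor CXCR4 (-0.72), PFKFB4 (-0.72), the recombination factor RAD51AP1 (-0.71), HIST2H2AA3 (-0.70) and GPR19 (-0.69). NME1-NME2 is a read-through locus and HIST2H2AA3 has a near-identical copy, so the assignment of reads to either is uncertain.

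Among passing protein-coding genes with a mean of at least 2 CPM, the largest rises were in FSD2 (1.57, SE 0.26), IQCN (1.47, SE 0.21), FRMPD1 (1.37, SE 0.19) and the heat-shock gene HSPA6 (1.34, SE 0.21). ZNF628 (1.30), the transcriptional corepressor SKI (1.29), the transcription factor KLF2 (1.23), PSD2 (1.22), PRR12 (1.22), ZNF865 (log2 fold change 1.2) and CCDC85B (1.19) followed. MXD4, which encodes a MAX-binding antagonist of MYC, had the smallest p-value of all genes and rose from 17.5 ± 1.1 to 41.0 ± 1.2 CPM (SD, n = 2 and 3; log2 fold change 1.23, SE 0.08, edgeR adjusted p = 0.0031). ZNF628, PRR12 and ZNF865, with GC contents of 70.8%, 66.7% and 70.9%, no longer passed after the GC correction, where their log2 fold changes were 0.81, 0.86 and 0.73. CCDC85B, with a GC content of 71.7%, still passed there at 0.68. ZNF628 also missed the threshold with upper-quartile scaling (1.32, adjusted p = 0.051). GPR19, with a GC content of 42.7%, narrowly missed it with the GC correction, at -0.58 (SE 0.14, adjusted p = 0.0538).

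Expression followed GC content differently in sgCDK6 libraries 1 and 2 than in the other 3 libraries. Across 10920 protein-coding genes, which are not independent replicates, the log2 fold change followed transcript GC content with a Spearman rho of 0.60. Genes in the GC-richest decile stood above those in the GC-poorest by 0.32 and 0.43 (log2) in sgCDK6 libraries 1 and 2, while this difference was -0.32 and -0.28 in the controls and -0.14 in sgCDK6 library 3. The GC-poorest decile held 1 higher and 96 lower genes, and the GC-richest held 163 higher and 1 lower. With the GC trend removed, 972 genes passed, and 603 of the 1008 genes kept their call and direction. The count of 1008 also depended on single libraries, being 23, 567 and 4769 without sgCDK6 library 1, 2 or 3. In these fits 4481, 4120 and 7268 genes had an unadjusted edgeR p under 0.05, against 5471 with all libraries. No tested gene among the 1008 turned direction in them. Leaving out control library 1 or 2 left a single control, and the log2 fold change of CDK6 was then -1.15 and -1.23.

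**Figure D2:**
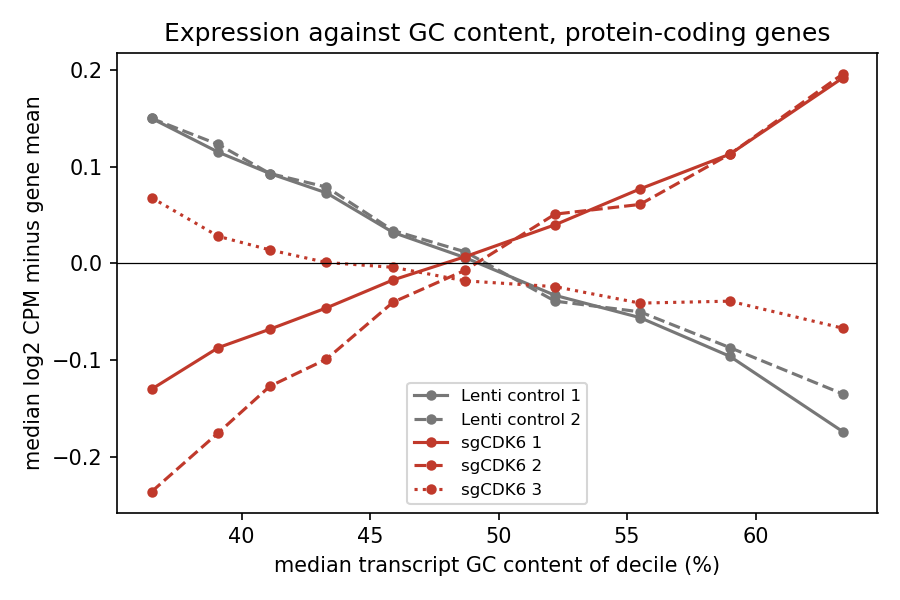
Median log2 CPM minus the gene mean (y axis) in deciles of transcript GC content (x axis, %) for protein-coding genes, with 1 line per library. In the GC-richest decile sgCDK6 libraries 1 and 2 lie at 0.19 and 0.20, the controls at -0.17 and -0.14, and sgCDK6 library 3 at -0.07.

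The next question was whether genes of the cell cycle, which CDK6 drives through G1, moved with it. Of 38 E2F target and DNA replication genes, 17 fell and none rose, and 22 were lower adjusted over the list alone. The primase subunit PRIM1 (-0.60, SE 0.08), the replisome genes GINS1 (-0.52, SE 0.07) and MCM10 (-0.53, SE 0.07) and the ribonucleotide reductase subunit RRM1 (-0.48, SE 0.07) were the clearest. The list's median log2 fold change was -0.34 (camera adjusted p = 2.2e-11, adjusted p = 0.415 with an estimated correlation). Of 29 G2/M and mitosis genes, 20 fell and none rose, and 22 were lower adjusted over the list alone. CDK1 went from 203 ± 8.5 to 122 ± 16 CPM (SD, n = 2 and 3), and the mitotic kinases NEK2 (-0.66) and TTK (-0.61) and topoisomerase TOP2A (-0.57) fell with it. This list's median was -0.41 (camera adjusted p = 2.2e-11, adjusted p = 0.415 with an estimated correlation). MKI67 (0.35, adjusted p = 0.231) and TYMS (0.53, adjusted p = 0.157), named after their values were seen, had positive log2 fold changes and did not pass.

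With the GC correction 23 E2F target genes and 17 mitotic genes were lower. In sgCDK6 library 3 alone, whose GC profile sloped the same way as the controls', the medians of these lists were -0.42 and -0.44. Its slope was shallower, so a GC trend against the controls remained. It stood at 0.07 against 0.15 in each control in the GC-poorest decile, and at -0.07 against -0.17 and -0.14 in the GC-richest. Lists matched on GC content, length and expression had medians of -0.08 and -0.10 in library 3. Leaving out 1 library at a time gave 0 to 22 lower genes in each list by edgeR, with none after either control library or sgCDK6 library 1 was left out. Without sgCDK6 library 3, 1 mitotic gene was higher.

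Among 23 replication-dependent histone genes, which are transcribed in S phase, 7 fell and none rose, and 15 were lower adjusted over the list alone. HIST1H4B (-0.65, SE 0.09), HIST1H4C (-0.55, SE 0.09), HIST1H4A (-0.49, SE 0.09) and HIST1H4H (-0.46, SE 0.08) had the smallest p-values, although reads of histone genes can be shared between similar copies. The list median was -0.33 (camera adjusted p = 2.0e-07, adjusted p = 0.58 with an estimated correlation), and 13 of them were lower with the GC correction. Leaving out 1 library at a time gave 0 to 10 lower and 0 to 1 higher histone genes by edgeR. Of 17 G1 cyclins, CDKs and inhibitors, 1 rose and 2 fell, and 1 was higher and 6 lower adjusted over the list alone. The pocket protein gene RBL1 (-0.43, SE 0.07) and the kinase gene CDK2 (-0.43, SE 0.07) fell, and CCND1, which encodes cyclin D1, rose from 0.673 ± 0.028 to 2.42 ± 0.64 CPM (SD, n = 2 and 3; log2 fold change 1.83, SE 0.26). The median of this list was -0.18 and its mean -0.01 (camera adjusted p = 0.0395, adjusted p = 0.451 with an estimated correlation). CDK4 (-0.15, adjusted p = 0.27) and CCND3 (0.02, adjusted p = 0.869) did not pass.

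**Figure D3:**
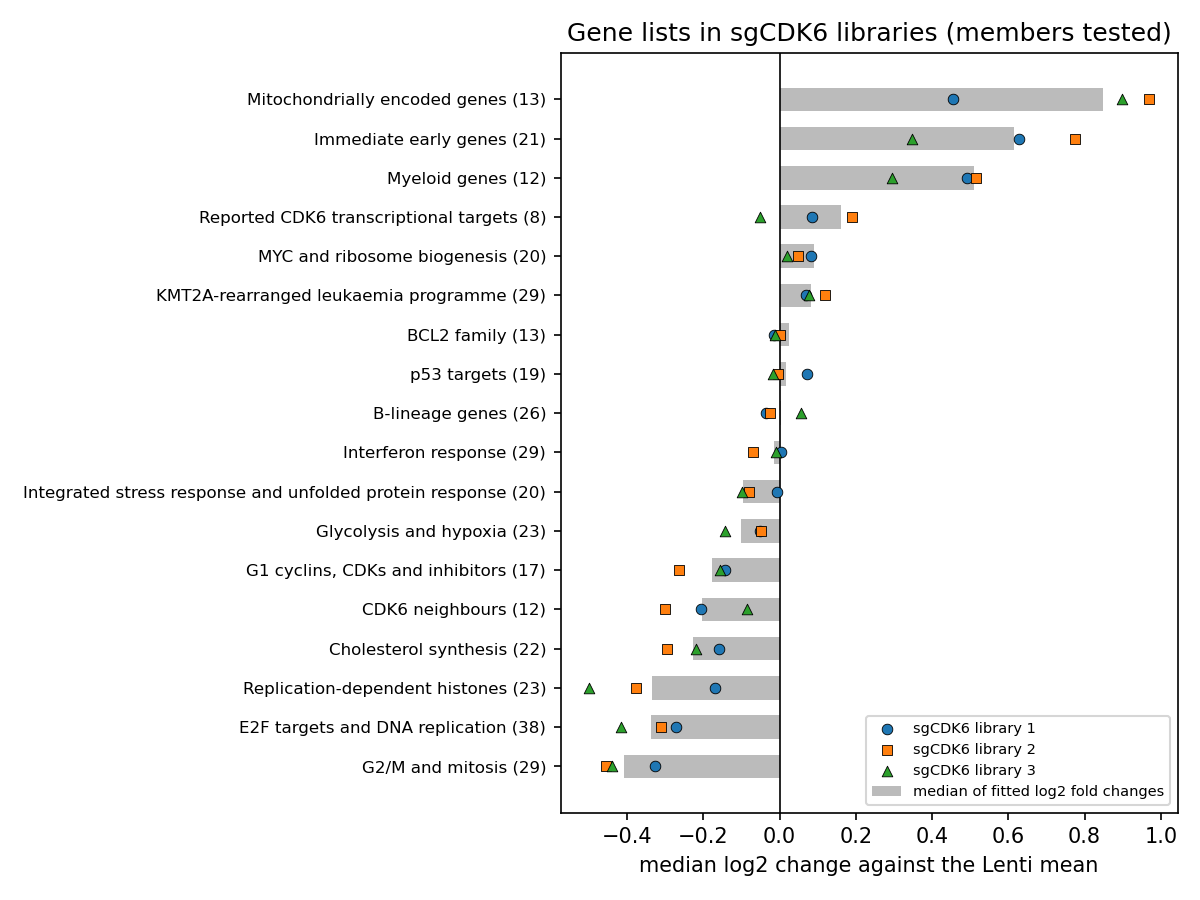
Median log2 change of the tested members of 18 gene lists (member number in brackets) in sgCDK6 against Lenti control libraries. Grey bars are medians of the fitted log2 fold changes and points are the 3 sgCDK6 libraries, each against the control mean; the G2/M list lies at -0.33, -0.46 and -0.44 and the immediate early list at 0.63, 0.78 and 0.35.

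Immediate early genes, which respond to growth factor and stress signals, moved the opposite way. Of 21 tested, 9 rose and none fell, and 17 were higher adjusted over the list alone. FOSB rose from 2.13 ± 0.32 to 4.36 ± 0.36 CPM (SD, n = 2 and 3; log2 fold change 1.03, SE 0.16), and ZFP36 (0.68, SE 0.14), JUNB (0.61, SE 0.11) and FOS (0.37, SE 0.07) also rose. The median was 0.61 (camera adjusted p = 7.9e-08, adjusted p = 0.415 with an estimated correlation). The list's members have a median GC content of 55.9%, and 7 of them were higher with the GC correction, where the median was 0.44, EGR1, EGR2 and IER2 no longer passed, and JUNB, with a GC content of 64.9%, stood at 0.31. Leaving out 1 library at a time gave 0 to 17 higher members by edgeR.

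Of the 13 protein-coding genes of the mitochondrial genome, 7 rose and none fell, and 12 were higher adjusted over the list alone. The complex I genes MT-ND5 (0.85, SE 0.12), MT-ND2 (0.68, SE 0.11), MT-ND1 (0.97, SE 0.17) and MT-ND4L (0.88, SE 0.16) had the smallest p-values. The median was 0.85 (camera adjusted p = 2.1e-05, adjusted p = 0.58 with an estimated correlation), and 8 were higher with the GC correction. MT-ND6, the gene encoded on the opposite strand, had 72.3 and 68.7 CPM in the controls, 28.7 and 26.2 CPM in sgCDK6 libraries 1 and 2 and 77.2 CPM in sgCDK6 library 3, and did not pass (log2 fold change -0.69, SE 0.40, adjusted p = 0.272). The share of counts in mitochondrial ribosomal RNA was 0.0922% and 0.0333% in the controls and 0.169%, 0.961% and 0.303% in sgCDK6 libraries 1, 2 and 3. Leaving out 1 library at a time gave 0 to 10 higher members by edgeR, and 1 member was lower without sgCDK6 library 3.

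Of 22 cholesterol synthesis genes, 5 fell and none rose, and 12 were lower adjusted over the list alone. The sterol-sensing regulator INSIG1 (-0.58, SE 0.08), the methylsterol oxidase MSMO1 (-0.48, SE 0.09), CYP51A1 (-0.47, SE 0.09) and the farnesyl diphosphate synthase FDPS (-0.38, SE 0.07) were lower in all sgCDK6 libraries. The median was -0.23 (camera adjusted p = 2.5e-04, adjusted p = 0.415 with an estimated correlation), and on the deposited TPM scale, where the median of all genes lay at 0.14 with log2(TPM + 1), it was 0.07, below that of all genes. With the GC correction 7 members were lower, and leaving out 1 library at a time gave 0 to 10 by edgeR. Of 23 glycolysis and hypoxia genes, ALDOC (-0.68, SE 0.08), PFKFB4 (-0.72, SE 0.12) and BNIP3 (-0.42, SE 0.09) fell and none rose, with 5 lower adjusted over the list alone. That list did not pass as a set (median -0.10, camera adjusted p = 0.0565), but it passed with the GC correction (median -0.09, camera adjusted p = 0.004, adjusted p = 0.352 with an estimated correlation).

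Among 29 genes of the KMT2A-rearranged leukaemia programme, HOXA3 (0.99, SE 0.18) and RUNX1 (0.67, SE 0.14) rose and none fell, and 6 were higher and 1 lower adjusted over the list alone. HOXA9 (0.08, SE 0.07, adjusted p = 0.449), MEIS1 (-0.08, SE 0.07, adjusted p = 0.463) and FLT3 (-0.32, SE 0.09, adjusted p = 0.0679) did not pass, and the list's camera adjusted p was 0.189 (median 0.08). With the GC correction 4 members were higher and the list passed (median 0.12, camera adjusted p = 0.0161, adjusted p = 0.44 with an estimated correlation), but it did not pass with GC and length correction (camera adjusted p = 0.0869). Leaving out 1 library at a time gave 0 to 8 higher and 0 to 3 lower members by edgeR. Of 8 genes reported as transcriptional targets of CDK6, EGR1 (1.02, SE 0.23) and RUNX1 rose and the kinase gene PIM1 (-0.55, SE 0.09) fell, with 4 higher and 2 lower adjusted over the list alone and a camera adjusted p of 0.886. EGR1 narrowly missed the threshold with the GC correction (0.92, SE 0.22, adjusted p = 0.0518) and with upper-quartile scaling (1.04, adjusted p = 0.0506). Of 26 B-lineage genes, CD79B (-0.49, SE 0.09) and IGLL1 (-0.60, SE 0.14), which encode parts of the B-cell receptor and its precursor, fell, and these 2 counts were the same adjusted over the list alone (camera adjusted p = 0.706). By edgeR 0 to 7 B-lineage genes were lower and 0 to 1 higher with 1 library left out, and IGLL1 missed the threshold with upper-quartile scaling (-0.58, adjusted p = 0.0534). Of 12 myeloid genes, CSF1R, the macrophage growth factor receptor, rose (0.67, SE 0.12), and 6 were higher adjusted over the list alone. The myeloid median was 0.51 (camera adjusted p = 0.0174, adjusted p = 0.415 with an estimated correlation), and 0 to 6 members were higher with 1 library left out. With the GC correction the median was 0.48 and the list did not pass (camera adjusted p = 0.0969), whereas it passed with GC and length correction (camera adjusted p = 0.0457).

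Of 29 interferon response genes, HERC5 (-0.46, SE 0.09), IFIT2 (-0.50, SE 0.11) and IFIT3 (-0.52, SE 0.12) fell, and 4 were lower adjusted over the list alone (camera adjusted p = 0.458). With the GC correction HERC5 still passed, while IFIT2 (-0.39, SE 0.10, adjusted p = 0.0634) and IFIT3 (-0.42, SE 0.10, adjusted p = 0.0533) did not, and IFIT3 also missed with upper-quartile scaling (adjusted p = 0.0535). No p53 target passed edgeR among 19, where 6 had an unadjusted p under 0.05, 2 were higher and 3 lower adjusted over the list alone, and DESeq2 called 2 higher and 3 lower (camera adjusted p = 0.886). CDKN1A, the p21 gene, stood at -0.34 (SE 0.08, adjusted p = 0.0513) and PLK3 at 0.57 (SE 0.14, adjusted p = 0.0537). After the GC correction 3 p53 targets were lower, CDKN1A among them (-0.48, SE 0.05, adjusted p = 0.0129), and CDKN1A also passed with RLE scaling (-0.35, adjusted p = 0.0497). No member of the BCL2 family passed among 13, where 2 had an unadjusted p under 0.05, 0 passed adjusted over the list alone and DESeq2 called 1 (camera adjusted p = 0.886). BMF stood at 0.25 (SE 0.07, adjusted p = 0.0631) and PMAIP1 at -0.37 (SE 0.15, adjusted p = 0.147). No MYC and ribosome biogenesis gene passed among 20, with 7 at an unadjusted p under 0.05, 0 adjusted over the list alone and 3 higher and 1 lower by DESeq2 (camera adjusted p = 0.471). MYC stood at 0.33 (SE 0.08, adjusted p = 0.0557) and POLR1A at 0.30 (SE 0.08, adjusted p = 0.0635). MYC passed with the GC correction (0.33, SE 0.07, adjusted p = 0.0409) and with upper-quartile scaling (0.35, adjusted p = 0.0495). No stress response gene passed among 20, with 7 at an unadjusted p under 0.05, 0 adjusted over the list alone and 1 higher and 3 lower by DESeq2 (camera adjusted p = 0.547). SESN2 stood at 0.48 (SE 0.13, adjusted p = 0.0598) and HSPA5 at 0.81 (SE 0.22, adjusted p = 0.0631). After the GC correction SHMT2 was lower and no other stress response gene passed. Of the T and NK cell, the erythroid and megakaryocyte, and the fibroblast and epithelial lists, 3 genes each were expressed highly enough to test, too few for a test of the list, none passed by edgeR or DESeq2 or adjusted over the list alone, and 0, 0 and 1 had an unadjusted p under 0.05. Their values included NKG7 (-0.06, SE 0.10), PRF1 (-0.38, SE 0.44), GP9 (0.10, SE 0.14), ITGA2B (0.31, SE 0.30), PDGFRB (0.15, SE 0.08) and COL1A1 (0.61, SE 0.26).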

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

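The corrections for GC content and length, the fit with sgCDK6 library 3 alone and the rescaled TPM were chosen after the data were seen, and the other alternatives were planned. No paired analysis was possible because the libraries carry no replicate numbers that link the groups. The fall of CDK6 kept its direction in every alternative run and passed in all of the count-based ones, at -1.15 to -1.23 when 1 library was left out, -1.02 with the GC correction and -1.16 with GC and length correction. It did not pass with limma on log2(TPM + 1) (-0.69, adjusted p = 0.165), log2(TPM + 0.1) (-0.70, adjusted p = 0.141) or rescaled TPM (-0.93, adjusted p = 0.06). The count of 1008 changed genes (546 higher, 462 lower) was 2710 with DESeq2 (1280 and 1430), 3694 with no filter (1933 and 1761), 11 with log2(TPM + 1) (5 and 6), 20 with log2(TPM + 0.1) (11 and 9), 18 against a fold of 1.2 and 1775 with library 3 alone (904 and 871). With rescaled TPM, limma called 0 genes (0 and 0), where 4425 had an unadjusted p under 0.05. Leaving out 1 library gave 11 to 4769 changed genes, 5 to 2315 higher and 5 to 2454 lower. A lone library in a group, control or sgCDK6 library 3, was assumed to vary like the other group. The count of changed CDK6 neighbours, 1 of 12, was 2 with DESeq2, 4 with no filter, 0 with each of the 3 TPM fits and 0 to 6 with 1 library left out. The 9 shifted lists became 0 with an estimated correlation and ranged from 8 to 10 with 1 library left out. The median of all genes lay at 0.02 in counts and at 0.14 (pseudocount 1) and 0.25 (pseudocount 0.1) in TPM, and there the cholesterol synthesis median turned from -0.23 to 0.074 and 0.076, still below the median of all genes. Where a cause is not given by fewer libraries or genes, the cause was not tested. Among the named genes and lists, 1229 comparisons with an alternative kept their direction and side of the threshold or, for counts of list members, were taken as unchanged. A move of the lower E2F targets from 17 to 23 with DESeq2 was taken as unchanged. Another 89 newly passed or grew, 443 no longer passed or shrank and 2 reversed. Of all 1008 changed genes, 25 turned direction with log2(TPM + 1), 25 with log2(TPM + 0.1), 2 with GC and length correction and 1 with rescaled TPM. Of 60754 genes, 24428 to 25515 had a count in a library and 17655 were tested, and what greater depth would add was not tested.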

Other observations

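The tests of the small RNAs and of the scale of TPM were chosen after the results were seen, as were the genes named in the next paragraphs. The tests of GC content, length and assigned transcript length were set before their outcomes were seen.

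Of 7 genes of MHC class II antigen presentation, picked after their values were seen and not tested as a list, 4 rose in sgCDK6 libraries. CIITA, the master regulator of class II transcription, rose from 118 ± 10.7 to 201 ± 26.4 CPM (SD, n = 2 and 3; log2 fold change 0.77, edgeR adjusted p = 0.0252). HLA-DQA1 (1.53) rose from a low level, 0.70 ± 0.06 to 2.03 ± 0.44 CPM (SD, n = 2 and 3). HLA-DMB (0.58) and HLA-DPB1 (0.47) also rose, while CD74 (0.31, adjusted p = 0.0543), HLA-DRA (0.12, adjusted p = 0.535) and HLA-DPA1 (-0.01, adjusted p = 0.949) did not pass. CPT1A, the enzyme that admits fatty acids into mitochondria, rose from 15.6 ± 0.38 to 29.0 ± 0.18 CPM (log2 fold change 0.90, edgeR adjusted p = 0.0073), and the cation channel gene TRPM2 rose (0.85, edgeR adjusted p = 0.007).

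Of 111 small nucleolar RNAs tested with edgeR, 20 fell and 0 rose, and 23 were lower with the GC correction. SNORD3A, the U3 RNA of ribosomal RNA processing, went from 16350 ± 3352 to 4440 ± 579 CPM (SD, n = 2 and 3; log2 fold change -1.88, edgeR adjusted p = 0.0066). The 4 U3 copies summed to 14260 and 19070 CPM in controls and 5255, 4325 and 4152 CPM in sgCDK6 libraries. The mitochondrial ribosomal RNAs MT-RNR1 (3.64, SE 1.01, adjusted p = 0.0648) and MT-RNR2 (2.73, SE 0.70, adjusted p = 0.0557) varied widely between libraries and did not pass.

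The 67 E2F target and mitotic genes had a median log2 fold change of -0.384. A GC and length bias between libraries would place them among lists matched on GC content, length and expression, but 95% of 10000 such lists lay between -0.15 and -0.06. In sgCDK6 library 3 the median was -0.42 against a matched range of -0.13 to -0.04. The immediate early list, at 0.615, also lay outside its matched range of -0.04 to 0.24. A response of the cell cycle to lower CDK6 remains a hypothesis for the former, which these tests of GC content and length do not address. The labels name no guide in the control libraries, so effects of carrying a guide cannot be told apart from those of lower CDK6. Other differences between the cultures or libraries were not tested, and no list passed with an estimated correlation.

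CDK6 fell less in TPM (-0.70) than in counts (-1.19), a log2 gap of 0.48. TPM is a count divided by an assigned length and a library scale, so these parts make up the gap by construction. The transcript length implied for CDK6 changed by -0.2068, inside the central 99% of 403 genes of similar count (-0.29 to 0.14) although 10 of them had a larger absolute change. Scatter in assigned length may thus account for the length part. Relative to the control mean this length was 0.851, 0.789 and 0.969 in sgCDK6 libraries 1, 2 and 3. Rescaling TPM to the median gene closed 51.06% of the gap and left 0.24, close in size to the length change. The bound of 50% was set when the size of the gap was already known, so passing it is marginal. Leaving out 6 abundant short RNAs closed 10.85%, which argues against their share of TPM, 55.7% and 56.8% in controls and 56.6%, 54.1% and 53.1% in sgCDK6 libraries, as the main source. A change in which CDK6 transcripts are made was not tested and stays open.

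A loss of small RNAs during library preparation, whatever their length, would lower other abundant small RNAs along with SNORD3A. The median log2 fold change of RN7SK, RN7SL1, RN7SL2, RMRP and RPPH1 was -0.09595 with the more abundant of the RMRP entries (-0.24). With both entries, the other at -0.62, the median was -0.14, still well above -1.88 for SNORD3A. This argues against a loss that acts alike on all these RNAs as the whole source of the fall in SNORD3A. It cannot decide on a loss limited to shorter RNAs, since the more abundant RMRP entry and RN7SK have 264 and 328 nt. The annotated SNORD3A entry is longer, at 699 nt, and the length of the SNORD3A RNA in these libraries was not measured. For the 60 snoRNAs outside the U3 family with a mean of at least 1 CPM and distinct counts, scaRNAs aside, the median was -0.36, against -0.25 for 31 other small noncoding RNAs of at most 350 nt. The difference was -0.1063 (two-sided permutation p = 0.353), and -0.11 (p = 0.316 by the same permutation test) when 1 scaRNA that missed these limits was left out, so for them a general loss of small RNAs stays open. Whether U3 responds to CDK6 was not tested by any other measurement here.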
